A study of Mus musculus with 6 samples.

How the data were processed

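RNA was measured in 6 samples of mouse splenic CD4+ T cells, 3 control and 3 mutant. Per the labels' protocols, RNA was taken with a silica column kit after 36 h of culture. Libraries were made from 1.0 µg of total RNA with a kit that removes ribosomal RNA and keeps transcripts without a poly(A) tail. The sequencer, the read length and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes such as Cd55os cannot be told apart from those of their partner. Per the submitters' processing notes, the builds GRCm39 and mm39 and the tools STAR 2.7.8a and Partek were used by the authors; the role of each and the annotation are not given in the sources used here. The deposited table holds estimated counts per gene, not normalized, under Ensembl gene IDs with symbols. It has 26469 gene rows and 1 column per library, and 57.8% of its values are whole (63.7% within 0.01 of a whole number). Fractions arise where a read is shared among genes or transcripts, so values of near-identical copies, as in the histone families and pseudogenes, are uncertain. Symbols were taken from the table, 863 rows without a symbol were named by their ID, and 32 rows sharing a symbol with a more abundant row were also named by ID. No coordinates are given, because the reference annotation at hand was of another build.

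The values were expected to be whole counts before the data were examined; being estimated counts, they were rounded to whole numbers, which left 54 rows at 0 in every library. Totals per library ran from 33633196 in control 1 to 43928723 in control 2. Mitochondrially encoded genes took 2.13 ± 0.13% and 2.20 ± 0.26% (SD, n = 3) of the counts in control and mutant libraries, and small structural RNA genes 2.49 ± 0.17% and 1.87 ± 0.49%. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 17.0 to 157), and each counted as 1 replicate. Within groups the common biological coefficient of variation was 0.297, with 0.226 among control and 0.35 among mutant libraries and 0.236 for mutant 2 and mutant 3 alone, so the added spread among mutant libraries lies with mutant 1.

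Analyses were run in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), which kept 18323 genes holding 99.92% of the counts. Libraries were scaled by TMM in edgeR 4.0.16 and compared, mutant minus control, with robust dispersion estimates and edgeR's quasi-likelihood test on all 6 samples without covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Intervals are 95% intervals from the standard error and the total degrees of freedom (residual plus prior) of the quasi-likelihood test. The standard error was the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2. Gene lists were compared with the other genes by camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, over the 28 of 31 lists with 5 or more tested members. The tests were repeated with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The level of a list in a library is the mean log2 CPM of its members minus the control mean.

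The 31 lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Sf3b1, Anapc13, Foxp3 and Map3k7 in any case. It then took up to 10 genes in each direction past the threshold with a mean log2 CPM of 1 or more and no overlap of groups, and up to 4 passing members of each list. Where fewer than 5 genes passed, as here, it took the 10 genes with the smallest p and 2 members of each list with the smallest p, as values only. Other genes are named as sets called in every fit, as markers of sex or cell type, or in the closing observations, and were chosen after their values were seen.

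The alternatives were DESeq2 1.42.0 with its own filtering, DESeq2 size factors or upper quartile scaling in edgeR, and limma-voom. Others were no count filter, a filter of 1 CPM in 3 samples, removal of mitochondrial and small structural RNA genes, the replicate number as a block, a threshold of 0.01, and leaving out each library in turn. DESeq2 gave no adjusted p to 10788 genes, which are not in its counts. The procedure was tested on simulated data with the observed spread for the comparison of mutant with control over 18323 genes, 100 of them changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those above a minimum level, and genes varied independently. The edgeR test recovered 35% of the 2-fold and 87% of the 4-fold changes with 9 false calls, and DESeq2 64% and 96% with 64 false calls. Camera recovered 20 of 20 shifted lists with 0 false calls among 20, in a simulation whose genes varied independently, which real genes do not.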

Results

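Gene expression was measured by RNA sequencing in 6 cultures of mouse splenic CD4+ T cells. Naive CD4+ T cells, which have not yet met their antigen, carried a conditional allele of Sf3b1, a core protein of the splicing machinery that recognises the branch point near the 3' splice site. In 3 samples, here called control, the cells came from mice without the Cd4-Cre recombinase and are annotated as wild type. In the other 3 samples, here called mutant, Cd4-Cre was present and the annotation is Sf3b1 mutation, the K700E change found in cancers. All 6 cultures were held for 36 h in TGF-β at 5 ng/ml with antibodies to CD3 and CD28, which activate T cells, and antibodies to IL-4 and IFNγ. This mixture drives naive cells towards regulatory T cells (Tregs). The deposited counts added up to 33633196, 43928723 and 36068040 in control 1, 2 and 3 and to 34524433, 34689302 and 36867312 in mutant 1, 2 and 3. Whether each sample came from a separate animal is not stated, so p-values measure only the spread between these samples, which may be technical in part, although the sex-linked genes place control 1 in another animal than the rest.

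The first question was whether the mutation altered the level of the genes that the series is about. Sf3b1 (ENSMUSG00000025982) was at 661 ± 44.3 CPM (the count relative to the scaled library total; SD, n = 3) in control and 627 ± 30.4 CPM in mutant cells. The log2 fold change was -0.075 ± 0.13 (SE), with a 95% interval from -0.38 to 0.23. Counts per gene do not show which allele the reads came from, so they do not check the genotype labels. Anapc13 (ENSMUSG00000035048), a subunit of the anaphase-promoting complex whose splicing is named in the series title, was at 10.1 ± 1.30 CPM in control and 9.49 ± 0.75 CPM in mutant cells (SD, n = 3). Its log2 fold change was -0.094 ± 0.19 (SE; 95% interval from -0.54 to 0.35). Foxp3 (ENSMUSG00000039521), the transcription factor that defines Tregs, was at 122 ± 15.6 CPM in control and 134 ± 90.0 CPM in mutant cells (SD, n = 3). Its 3 mutant values were far apart, at 230, 118 and 52.3 CPM in mutant 1, 2 and 3, and the 95% interval of the log2 fold change of 0.13 ± 0.45 (SE) ran from -0.91 to 1.17. Without mutant 1 the Foxp3 log2 fold change was -0.51, and without mutant 3 it was 0.51. Map3k7 (ENSMUSG00000028284), a kinase of the TGF-β and NF-κB pathways reported as mis-spliced with mutant SF3B1, was at 296 ± 46.9 CPM in control and 303 ± 22.1 CPM in mutant cells (SD, n = 3). Its log2 fold change was 0.037 ± 0.16 (SE). None of the 4 genes passed edgeR's quasi-likelihood test (adjusted p from 0.888 for Sf3b1 to 0.954 for Map3k7).

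**Figure D1:**
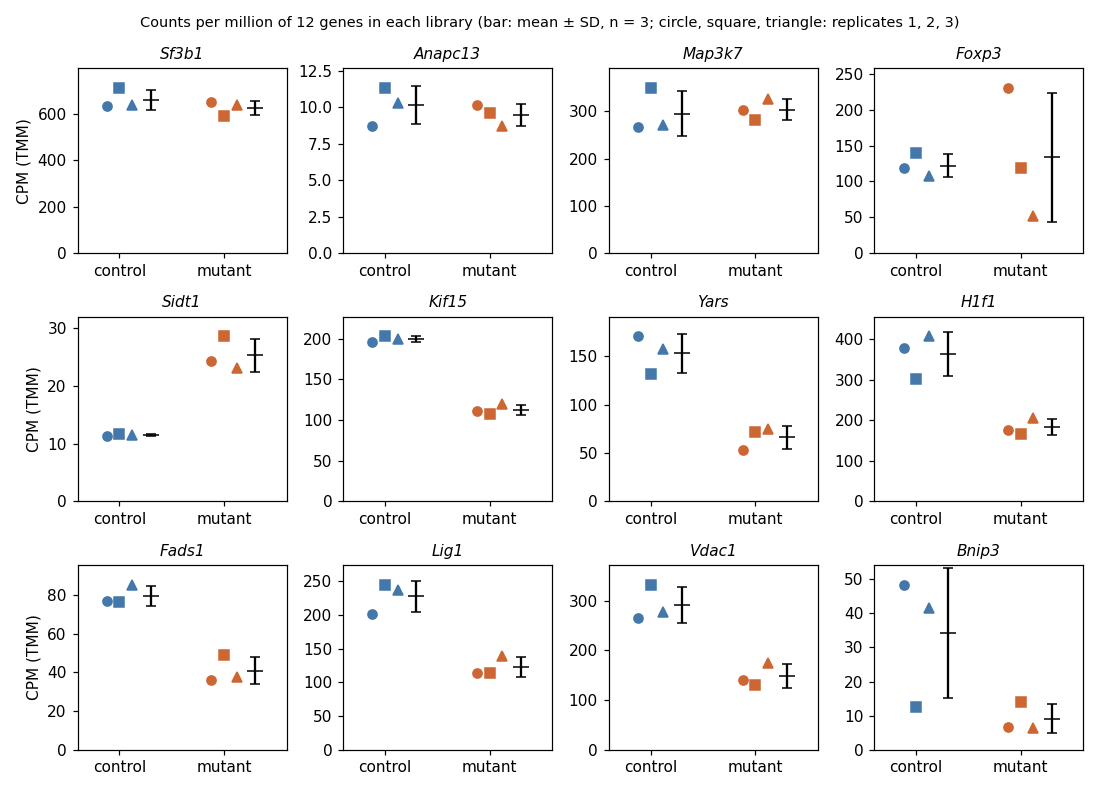
CPM values, scaled by TMM factors, of 12 genes in each of the 6 libraries (blue, control; orange, mutant; circle, square and triangle for replicates 1, 2 and 3). Bars beside the points give the mean and SD of each group. Foxp3 spans 52.3 to 230 CPM among the mutant libraries, while for Sidt1, Kif15, Yars, H1f1, Fads1, Lig1 and Vdac1 the 3 control and 3 mutant points do not overlap.

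Of the 10 genes with the smallest p-values, 6 were measured lower and 4 higher in every mutant than in every control library. Kif15, a mitotic kinesin, was at 199 ± 3.21 CPM in control and 113 ± 6.30 CPM in mutant cells (SD, n = 3). Lig1, the DNA ligase of replication, was at 228 ± 23.1 and 123 ± 14.6 CPM, and the linker histone gene H1f1 at 362 ± 53.8 and 182 ± 19.9 CPM. Yars, which encodes tyrosyl-tRNA synthetase, was at 153 ± 20.1 and 66.2 ± 11.7 CPM. The fatty acid desaturase gene Fads1 was at 79.5 ± 5.05 and 40.8 ± 7.03 CPM, and Vdac1, a channel of the outer mitochondrial membrane, at 292 ± 35.8 and 149 ± 23.3 CPM. Log2 fold changes of these 6 genes ran from -1.21 ± 0.18 (SE) for Yars to -0.82 ± 0.12 for Kif15. Measured higher in every mutant library were Sidt1, a gene for a transmembrane protein, at 11.5 ± 0.21 CPM in control and 25.4 ± 2.88 CPM in mutant cells, Tbc1d30 and Fhip1a. Tbc1d30 was at 8.39 ± 1.77 and 20.5 ± 3.48 CPM and Fhip1a at 0.386 ± 0.048 and 2.28 ± 0.56 CPM. Slc6a12, which encodes a transporter of betaine and GABA, was at 0.028 ± 0.029 CPM in control, near the limit of detection, and 1.08 ± 0.62 CPM in mutant cells. By edgeR's quasi-likelihood test 0 of 18323 genes passed an adjusted p of 0.05. The 10 genes above all had an adjusted p of 0.598 in edgeR, while 1396 genes (7.62%) had an unadjusted p under 0.05. With the libraries regrouped so that each side held control and mutant samples, edgeR had up to 1255 such genes. By limma-voom 0 genes passed and 1297 had an unadjusted p under 0.05. DESeq2 called 100 genes, 52 higher and 48 lower in mutant cells, among them 9 of the 10 (Slc6a12 received no adjusted p). All 100 had the same direction and an unadjusted p under 0.05 in edgeR, and in 96 of them the groups did not overlap. DESeq2 had chosen these genes on the same counts, so this is no independent support for them. In simulated data with the observed spread DESeq2 made 64 false calls. With control 1, control 3 and mutant 1 set against the rest it called 83 genes. Across all genes tested the groups did not overlap in 2580 (14.1%, where chance gives 10%), 1210 higher and 1370 lower in mutant cells. The DESeq2 count moved with single libraries, being 13 without control 1, 17 without control 3, 215 without mutant 1 and 374 without mutant 3. So did its balance, with 268 higher and 106 lower without mutant 3 and 45 higher and 98 lower without mutant 2. The 7 genes called on all 6 libraries and in each of the 6 fits that left out 1 library were Sidt1, Pigr, Yars, Cdcp1, Fhip1a, Cd55os and ENSMUSG00000121393. These fits share most of their libraries and are not independent. Cdcp1 was near the limit of detection in control, at 0.064 ± 0.043 CPM against 1.46 ± 0.98 CPM in mutant cells. So was ENSMUSG00000121393, at 0.23 ± 0.093 and 1.91 ± 0.95 CPM.

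Genes of glucose use, sterol synthesis and the amino acid stress response had lower mean levels in mutant than in control libraries. All 20 tested members of the glycolysis and hypoxia list had a lower mean in mutant cells, with a mean log2 fold change of -0.83, and in 12 of them every mutant library lay below every control library. Bnip3, a hypoxia-inducible mitophagy receptor, was at 34.2 ± 19.0 CPM in control and 9.10 ± 4.29 CPM in mutant cells (SD, n = 3). The phosphofructokinase gene Pfkp was at 312 ± 99.3 and 162 ± 37.4 CPM, and both genes overlapped between the groups. All 19 members of the sterol synthesis list were lower, with a mean log2 fold change of -0.62 and 15 members whose groups did not overlap. Among them, Mvd, an enzyme of the mevalonate pathway, was at 36.9 ± 4.48 and 21.1 ± 3.93 CPM, and Dhcr7, which catalyses the last step to cholesterol, at 92.7 ± 9.02 and 50.5 ± 13.4 CPM. In the list for ATF4, a transcription factor induced by amino acid shortage, and the unfolded protein response, 20 of 21 members were lower, with a mean log2 fold change of -0.82 and 8 without overlap. Slc3a2 and Slc7a5, the subunits of a carrier for large amino acids, were at 164 ± 28.0 and 391 ± 51.6 CPM in control and at 96.3 ± 22.2 and 203 ± 68.8 CPM in mutant cells. Camera, with its preset correlation between genes, placed these lists below other genes with adjusted p = 5.26e-11 for glycolysis, 5.72e-11 for sterol synthesis and 7.48e-09 for ATF4. With an estimated correlation the camera adjusted p = 0.736 for each of them. Over all genes tested no member passed edgeR's test; adjusted over the list alone, 0 glycolysis, 4 sterol and 5 ATF4 members passed. Mutant 1 had the lowest mean level of each list, and without it the sterol mean was -0.36 (camera adjusted p = 1.38e-07). Control 2 had the lowest glycolysis and ATF4 levels among the controls, at -0.33 and -0.43 on the log2 scale relative to the control mean, against -0.50 and -0.26 in mutant 2.

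Smaller shifts were measured in the nuclear genes of oxidative phosphorylation, 22 of 25 of which were lower (mean log2 fold change -0.14), and in ribosome biogenesis, where 21 of 22 were lower (-0.28). Ndufv1, a subunit of complex I, was at 55.7 ± 5.79 CPM in control and 40.3 ± 5.02 CPM in mutant cells and Uqcrc2 of complex III at 163 ± 21.5 and 139 ± 14.6 CPM. The nucleolar gene Npm1 was at 1413 ± 149 and 1099 ± 393 CPM and Gar1 at 60.5 ± 11.2 and 44.9 ± 18.4 CPM. Camera gave adjusted p = 0.0166 for oxidative phosphorylation and 0.00301 for ribosome biogenesis, and adjusted p = 0.802 with an estimated correlation for both. Both calls ended when single libraries were left out, with camera adjusted p = 0.88 without control 2 and 0.286 without mutant 1 for oxidative phosphorylation, and 0.268 and 0.897 for ribosome biogenesis. The oxidative phosphorylation mean was -0.029 without control 2 and the ribosome biogenesis mean 0.011 without mutant 1. The 13 mitochondrially encoded genes had a mean log2 fold change of -0.068 (camera adjusted p = 0.693), and 0.12 without mutant 1. In this list mt-Co3 was at 1164 ± 151 and 1367 ± 126 CPM and mt-Atp8 at 192 ± 7.41 and 172 ± 34.1 CPM. No member of these 3 lists passed edgeR's test over all genes or adjusted over the list alone.

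Genes of the cell division cycle also had lower mean levels in mutant than in control libraries, with list calls that depended on camera's preset correlation. Replication-dependent histone transcripts, made in S phase without a poly(A) tail, are kept by ribosomal RNA depletion. All 14 tested genes had lower means in mutant cells, with a mean log2 fold change of -0.54 and 11 members without overlap. H1f4, a second linker histone gene, was at 434 ± 14.6 CPM in control and 281 ± 25.6 CPM in mutant cells. All 25 members of the G2-M and mitosis list were lower, by a mean log2 fold change of -0.28 with 10 members without overlap. The kinetochore genes among them were Cenpe at 267 ± 10.0 and 187 ± 30.7 CPM and Bub1 at 120 ± 5.81 and 83.5 ± 17.1 CPM. All 28 members of the G1-S and replication list had lower means, by -0.25 on average. Without mutant 1 the G1-S mean was -0.10 (camera adjusted p = 0.0432), and the level of mutant 3, at 0.049, lay above those of control 1 (-0.14) and control 3 (-0.014). The DNA polymerase genes Pole and Pola1 were at 235 ± 9.04 and 177 ± 2.16 CPM in control and 180 ± 19.4 and 125 ± 27.4 CPM in mutant cells. Camera adjusted p-values were 8.33e-11 for histones, 2.05e-07 for G2-M and 1.32e-05 for G1-S, and with an estimated correlation the adjusted p = 0.736, 0.736 and 0.802. No member passed edgeR's test over all genes, and 9 histone genes, 0 G2-M, 0 G1-S and 0 anaphase-promoting complex genes passed adjusted over the list alone. Of 16 genes of the anaphase-promoting complex and its activators, 13 were lower, by a mean of -0.12 (camera adjusted p = 0.0961, 0.0135 without control 1 and 0.785 without control 2, where the mean was -0.044). Anapc5 was at 357 ± 53.1 and 282 ± 12.7 CPM and Cdc16 at 70.0 ± 6.08 and 55.8 ± 6.0 CPM.

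The mean level of each list in each library, relative to the control mean, was compared between the groups by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 samples against 3. This exact test was not among those fixed beforehand. The groups did not overlap for 5 of the 28 lists, each at that smallest exact p of 0.1. Chance gives 10% for each list, and the lists were read in the same libraries. Glycolysis ran from -0.33 to 0.25 in control and from -1.23 to -0.50 in mutant libraries on the log2 scale, and sterol synthesis from -0.12 to 0.16 and from -1.13 to -0.32. Histones ran from -0.074 to 0.044 and from -0.73 to -0.29 and G2-M from -0.15 to 0.18 and from -0.45 to -0.16. The fifth was the Th17 list, higher in mutant libraries at 0.71 to 2.28 against -0.48 to 0.62.

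**Figure D2:**
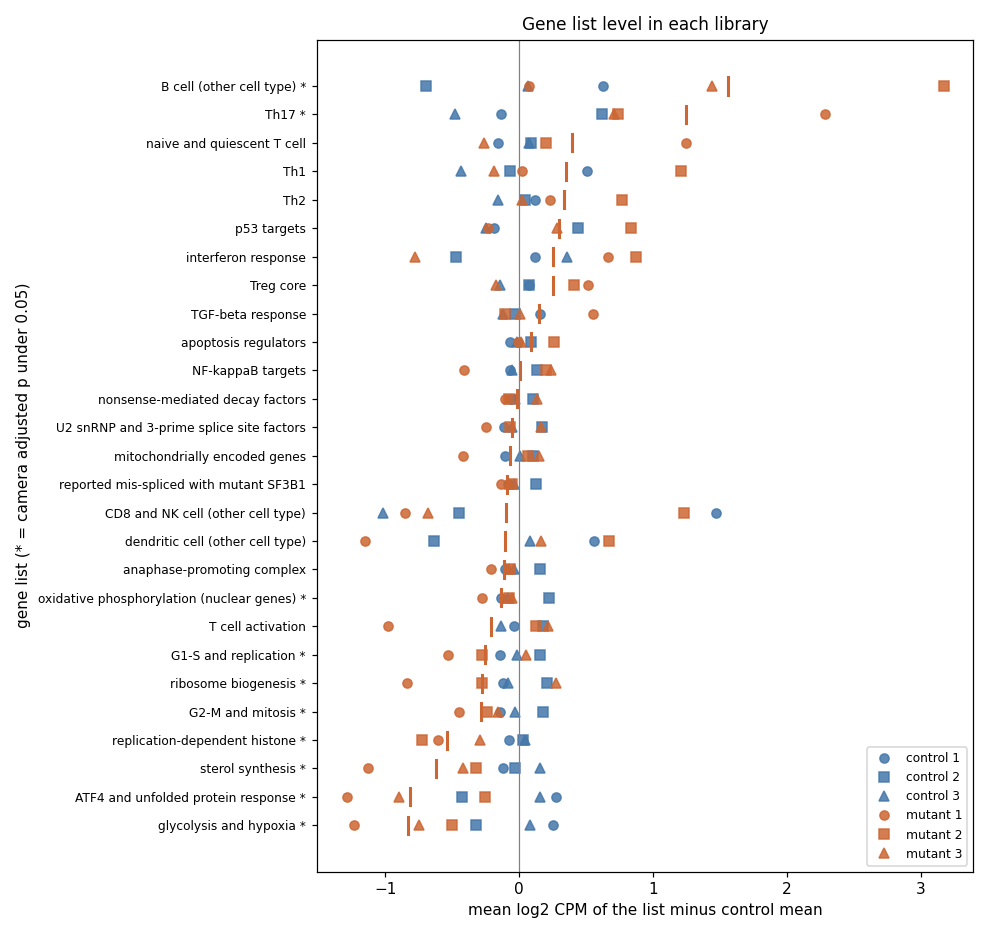
Mean log2 CPM of the members of 27 gene lists (sex-linked genes left out) in each library, as the difference from the control mean (x axis, log2 units; blue, control; orange, mutant; vertical bar, mutant mean; asterisk, camera adjusted p under 0.05 with the preset correlation). Mutant libraries lie below control libraries for glycolysis, sterol synthesis, histones and G2-M, and mutant 1 is the lowest point for T cell activation at -0.98.

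For Treg differentiation, 21 of 26 genes of the Treg core list had higher and 5 lower means in mutant cells, with a mean log2 fold change of 0.25. The Treg mean was 0.13 without mutant 1 and 0.46 without mutant 3. The list did not pass camera's test (adjusted p = 0.25), but did so without mutant 3 (camera adjusted p = 0.0233, higher), the library with the lowest Foxp3. Itgae, the αE integrin subunit induced by TGF-β, was at 4.30 ± 2.90 CPM in control and 15.1 ± 13.3 CPM in mutant cells. Izumo1r, a folate receptor family gene used as a Treg marker, was at 51.5 ± 3.31 and 34.2 ± 14.0 CPM. The 21 tested genes of the TGF-β response had a mean log2 fold change of 0.15 (camera adjusted p = 0.633), and -0.036 without mutant 1. Tgif1 was at 71.9 ± 9.67 and 105 ± 47.2 CPM. Of 9 tested Th17 genes, 8 were higher in mutant cells, with a mean log2 fold change of 1.24 and camera adjusted p = 0.00798. The camera adjusted p = 0.736 with an estimated correlation, and 0.123 without mutant 1, where the Th17 mean was 0.735. Levels were low, the chemokine gene Ccl20 being at 0.717 ± 0.508 and 12.5 ± 16.8 CPM, with 32.0 CPM in mutant 1. The cytokine gene Il17a was at 0.138 ± 0.135 and 0.965 ± 0.761 CPM. The 13 Th1 genes (mean log2 fold change 0.35, camera adjusted p = 0.482) and 9 Th2 genes (0.34, 0.123) did not pass, and without mutant 2 the Th1 mean was -0.064 and the Th2 mean 0.14. Of the Th1 genes, Il18rap was at 11.9 ± 6.48 and 37.1 ± 29.9 CPM and Cxcr3 at 2.21 ± 0.78 and 4.32 ± 1.47 CPM. Of the Th2 genes, Gata3 was at 63.7 ± 8.80 and 94.97 ± 32.7 CPM and Ccr8 at 65.3 ± 16.8 and 88.8 ± 17.8 CPM. No member of these 5 lists passed edgeR's test over all genes or adjusted over the list alone.

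Genes of T cell activation and of the naive state differed mainly in 1 library. The activation list had a mean log2 fold change of -0.21 (camera adjusted p = 0.0581) and a level of -0.98 in mutant 1 against 0.13 and 0.21 in mutant 2 and 3. The naive and quiescent list had a mean of 0.39 (camera adjusted p = 0.072) and a level of 1.25 in mutant 1 against 0.20 and -0.26. The activation list passed when any of 4 single libraries was left out (camera adjusted p from 0.00267 without mutant 3 to 0.0236 without control 3, with 0.0157 without control 1 and 0.00624 without mutant 2). Its camera adjusted p was 0.688 without mutant 1, with the opposite direction. On all 6 libraries it passed without a count filter (camera adjusted p = 0.0329) and without mitochondrial and small structural RNA genes (0.0468). The naive list passed without control 2 (0.0375), mutant 2 (0.0375) or mutant 3 (0.00337) and had a camera adjusted p of 0.568 without mutant 1, again with the opposite direction. With the filter of 1 CPM in 3 samples the naive list passed too (camera adjusted p = 0.0476). Irf4, a transcription factor induced by the T cell receptor, was at 1009 ± 51.0 CPM in control and 683 ± 93.9 CPM in mutant cells without overlap. Xcl1 was at 0.990 ± 0.761 and 2.57 ± 1.36 CPM. Pdlim4 was at 0.791 ± 0.401 and 4.23 ± 4.12 CPM and Slfn2, a quiescence factor of T cells, at 135 ± 57.5 and 224 ± 44.9 CPM. No member of either list passed edgeR's test over all genes or adjusted over the list alone.

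Of the other signalling lists, NF-κB targets had a mean log2 fold change of 0.0061 and a median of -0.082 (camera adjusted p = 0.769, and 0.0159, higher, without mutant 1). Without mutant 3 the NF-κB mean was -0.11. Member means differed in direction, Traf1 being at 95.2 ± 5.87 CPM in control and 153 ± 18.5 CPM in mutant cells and Lta, which encodes lymphotoxin α, at 386 ± 45.1 and 189 ± 69.5 CPM. Adjusted over the list alone 1 of the 19 passed edgeR's test, and over all genes none did. Of 23 p53 targets 20 were higher, with a mean of 0.29 (camera adjusted p = 0.0959, 0.00143 without control 2 and 3.32e-05 without mutant 1). Without mutant 2 the p53 mean was 0.043, with camera direction lower (adjusted p = 0.874). The antiproliferative gene Btg2 was at 52.8 ± 19.7 and 131 ± 49.3 CPM and Rrm2b at 28.9 ± 2.34 and 19.6 ± 2.64 CPM. The interferon response had a mean of 0.25 (camera adjusted p = 0.266, and 9.4e-05, higher, without mutant 3). The interferon mean was -0.038 without mutant 2 and 0.014 without control 2. Zbp1 was at 2.56 ± 0.59 and 6.33 ± 4.53 CPM and Gbp3 at 1.49 ± 0.28 and 3.35 ± 2.98 CPM. Apoptosis regulators had a mean of 0.088 (camera adjusted p = 0.693), and 0.024 without mutant 2. The proapoptotic gene Bcl2l11 was at 24.8 ± 7.99 and 64.5 ± 42.2 CPM and Mcl1, which opposes it, at 244 ± 24.9 and 342 ± 92.3 CPM. No p53, interferon or apoptosis gene passed edgeR's test over all genes or adjusted over the list alone.

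None of the 3 lists of splicing and RNA decay genes passed camera's test on all 6 libraries. The 23 genes of the U2 snRNP and of 3' splice site recognition had a mean log2 fold change of -0.052 (camera adjusted p = 0.406, and 0.0132, lower, without mutant 3), and a mean of 0.058 without mutant 1. Rbm17 was at 110 ± 7.82 CPM in control and 93.0 ± 21.3 CPM in mutant cells and Zrsr2 at 37.2 ± 1.31 and 41.3 ± 2.86 CPM. The 13 genes reported as mis-spliced with mutant SF3B1 had a mean of -0.091 (camera adjusted p = 0.266), and -0.032 without control 2. Tti1 was at 56.0 ± 0.44 and 47.3 ± 6.10 CPM and Serbp1 at 878 ± 64.0 and 708 ± 201 CPM. The 14 factors of nonsense-mediated decay, which removes transcripts with early stop codons, had a mean of -0.017 and a median of 0.035 (camera adjusted p = 0.849). Their mean ran from -0.096 without mutant 3 to 0.039 without mutant 1. Rbm8a was at 93.9 ± 9.08 and 77.2 ± 16.8 CPM and Magoh at 53.8 ± 10.2 and 44.6 ± 12.2 CPM. No member of these 3 lists passed edgeR's test over all genes or adjusted over the list alone. Splice junctions and isoforms were not analysed here.

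Markers of other cell types differed between single libraries. All 11 tested B cell genes had higher means in mutant libraries, with a mean log2 fold change of 1.56 (camera adjusted p = 0.000149, and adjusted p = 0.736 with an estimated correlation). The mean was 0.77 without mutant 2 and 2.32 without mutant 1. With the filter of 1 CPM in 3 samples it was 0.85 (camera adjusted p = 0.0382). Adjusted over the list alone 2 passed edgeR's test and over all genes none did. Blk was at 0.057 ± 0.049 CPM in control and 0.832 ± 0.506 CPM in mutant cells and Cd79a, part of the B cell receptor, at 0.741 ± 0.243 and 3.06 ± 1.82 CPM. The list level was 3.17 in mutant 2 and 1.44 in mutant 3 against 0.073 in mutant 1 and -0.70 to 0.63 in control libraries. The 5 tested CD8 and NK cell genes had a mean of -0.10 (camera adjusted p = 0.769), which ran from -0.75 without mutant 2 to 0.63 without control 1. Cd8a was at 24.3 CPM in control 1 and at 0.424 to 8.95 CPM elsewhere and Cd8b1 at 16.0 CPM in control 1 and 4.59 to 8.33 CPM elsewhere. The 6 dendritic cell genes had a mean of -0.11 and a median of 0.27 (camera adjusted p = 0.995), and the mean ran from -0.48 without mutant 2 to 0.43 without mutant 1. Batf3 was at 3.45 ± 3.21 and 0.681 ± 0.687 CPM and Ccr9 at 1.18 ± 0.55 and 1.94 ± 0.89 CPM. No gene of the CD8 and NK cell or dendritic cell lists passed edgeR's test over all genes or adjusted over the list alone. Too few macrophage, erythroid and neutrophil genes were above the count filter for a list test. Ctss was at 67.3 ± 7.70 and 98.5 ± 58.8 CPM and Cd68 at 1.00 ± 0.40 and 1.18 ± 0.26 CPM. Alas2 was at 0.472 ± 0.268 and 0.622 ± 0.252 CPM and Itga2b at 0.980 ± 0.508 and 1.20 ± 0.76 CPM. Among neutrophil genes, Camp had 1 to 3 counts per library.

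Control 1 differed from the other 5 libraries in genes of the sex chromosomes. Xist, transcribed from the inactive X chromosome of females, had 119670 counts in control 1 and 4.89 to 23.7 estimated counts in the others. The Y-linked genes Ddx3y and Eif2s3y had 0 counts in control 1 and 2174 to 4283 in the others, and Kdm5d had 1 count in control 1 and 2323 or more in the others. Control 1 therefore did not come from the same animal as any other library. Every mutant library had Y-linked transcripts, so sex was not balanced between the groups. Its part in their differences was not tested apart from other traits of control 1. Without control 1 only libraries with Y-linked transcripts remained, and DESeq2 called 13 genes on those 5. The mean log2 fold change was then -0.71 for glycolysis, -0.69 for sterol synthesis, -0.68 for ATF4 and -0.58 for histones. The 5 sex-linked genes as a list did not pass camera's test (adjusted p = 0.374), and their mean turned from 1.59 to -0.25 without control 1.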

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

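The fits with the B cell marker level as a covariate, those without control 1 and mutant 1 together, and the DESeq2 fits without single libraries were chosen after the data were examined. Of 1217 comparisons of 72 named genes with an alternative, 1180 kept their direction and side of the threshold and 15 passed only with DESeq2. No gene passed in edgeR or limma-voom under the other alternatives, with 618 to 2426 genes at an unadjusted p under 0.05 in edgeR. DESeq2 called 100 (52 higher, 48 lower), and the B cell covariate in edgeR gave 11 (3 higher, 8 lower). DESeq2 calls ran from 13 (without control 1) to 374 (without mutant 3). Camera's 8 lower and 2 higher lists became 0 and 0 with an estimated correlation (smallest adjusted p = 0.736) and 0 and 0 with fry (smallest adjusted p = 0.32). Higher lists numbered 2 to 5 when single libraries were left out. The replicate numbers do not pair the samples (r of deviations -0.048, -0.067 and -0.029 for numbers 1, 2 and 3). With a replicate block 0 genes passed in edgeR (991 at an unadjusted p under 0.05), and camera called 9 lists lower, T cell activation added (adjusted p = 0.0159), and 3 higher, p53 targets added (0.0121). Without control 1 and mutant 1 together 7 lists were lower and 2 higher, the Th17 (0.307) and ribosome biogenesis lists (0.307) no longer passing and p53 targets (0.00286) passing.

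Genes whose direction turned did not pass the test in either fit, and the cause was not tested. With the B cell covariate the log2 fold changes were 0.016 for Sf3b1, 0.0027 for Anapc13 and -0.42 for Alas2. The B cell list lost its shift by construction (camera adjusted p = 0.983). The dendritic cell (0.0207) and T cell activation lists (0.0026) passed lower, the dendritic mean of -0.11 without the covariate being already negative with camera direction higher. The TGF-β response (0.0207) and naive lists (0.000484) passed higher, and oxidative phosphorylation no longer passed (0.221). Foxp3 was at -0.11 with limma-voom, -0.11 with the replicate block and -0.54 without control 1 and mutant 1 together, where Map3k7 was at -0.030, Cd8b1 at 0.24, Cd8a at 1.90, Ctss at -0.12 and Cd68 at -0.087. Cd8a was at 0.47 with the replicate block. When single libraries were left out, log2 fold changes ran from -0.51 to 0.51 for Foxp3, -0.037 to 0.17 for Map3k7, -0.23 to 0.013 for mt-Atp8 and -0.76 to 0.22 for Cd8b1. They ran from -1.84 to 1.37 for Cd8a, -0.041 to 0.82 for Ctss and -0.28 to 0.69 for Itga2b. Scaling alternatives moved the median log2 fold change of all genes by 0.033 or less. A simulated 2-fold change was recovered by edgeR in 35% of cases, so changes of that size can be missed at this spread. The simulated changes left out genes of the lowest levels and genes varied independently, so the share itself need not hold for these data.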

Other observations

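The 3 gene groups described first were put together after the genes called by DESeq2 had been seen. The tests of depth, of the B cell level in mutant 1, of B cells in mutant 2 and mutant 3, of mutant 1 alone, of oxygen supply and of the edgeR splits were chosen after the result was seen. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 19 had lower means in mutant cells (mean log2 fold change -0.54) and in 13 the groups did not overlap. Of the 20, 2 (Aars and Sars) are also in the ATF4 list. The level of the synthetase group was -0.94 in mutant 1 against -0.35 and -0.32 in mutant 2 and mutant 3. Lars was at 242 ± 31.2 CPM in control and 135 ± 40.9 CPM in mutant cells (SD, n = 3) and Gars at 356 ± 37.8 and 216 ± 56.3 CPM. Qars was at 132 ± 20.01 and 137 ± 6.44 CPM. Of 19 genes of fatty acid synthesis and desaturation, 17 were lower (mean -0.81), 11 of them without overlap. Their largest differences in CPM were those of the desaturase genes Scd2, at 2855 ± 213 and 1296 ± 862 CPM, and Scd1, at 815 ± 189 and 172 ± 197 CPM. Srebf1, which encodes a transcription factor of lipid synthesis, was at 113 ± 1.61 and 74.9 ± 14.9 CPM. All 18 hypoxia-inducible genes, 4 of them also in the glycolysis list, had lower means (mean -0.73). Control and mutant libraries did not overlap for 4 of the 18, including Egln1 at 77.8 ± 7.02 and 57.6 ± 0.98 CPM and P4ha1 at 90.9 ± 12.6 and 55.7 ± 7.34 CPM, and the log2 fold change of Ddit4 was -0.0034. Camera with the preset correlation gave adjusted p = 2.26e-10, 5.997e-10 and 7.95e-08 for the 3 groups. With an estimated correlation the camera adjusted p = 0.123, 0.0812 and 0.0812. The gene groups hold 1, 4 and 2 genes called by DESeq2, after which they were put together, so these p-values decide nothing and a shift of each group as a whole stays open.

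With 3 samples against 3 there are 10 splits, too few for a share under 0.05. By edgeR 0 genes passed in every split. Since the real split gave 0, any split matches it, and that count carries no information. At an unadjusted p under 0.05 edgeR had 1396 genes in the real split and 229 to 1255 in the others. DESeq2 called 100 genes in the real split and at most 83 in another, and 1 of the 10 splits, the real one, gave as many. Camera called 10 lists in the real split and at most 19 in another, that of control 1, mutant 1 and mutant 2 against the rest, and 8 of the 10 splits gave as many.

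Mutant 1 stood apart from the other 5 libraries, at 89.8 on the first principal component (41% of the variance) against -24.6 to -7.10. It combined the highest Foxp3 (230 CPM) and Ccl20 (32.0 CPM) with the lowest levels of the activation (-0.98) and ribosome biogenesis lists (-0.84) and the highest naive list (1.25). Against depth, 1 library had a lower total count than mutant 1 and the other 4 a higher one, and after structural RNA and mitochondrial genes were removed its gap to the nearest library was still 0.847 of the range. Its B cell list level of 0.0735 lay within the control range, against B cell transcripts as the source. A weaker or later activation of this culture may account for the pattern but was not tested, nor was a biological explanation by group, since mutant 2 and 3 did not share it.

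B cell markers were high in mutant 2 and mutant 3, where Pax5 had 406 and 62 counts against 1 to 27 in the other libraries and Igkc 431 and 83 against 11 to 19. Cd74, abundant in B cells but also read in every library, was at 166 and 105 CPM against 69.9 to 72.7 CPM. Of 10 genes of the B cell list fixed beforehand, 7 lay above the control mean in both libraries, with mutant 2 to mutant 3 ratios of that excess from 2.79 for Blk to 12 for Ms4a1, and 3, Cd79b, Ighm and Ighd, did so in mutant 2 only. Ighm was at 132 to 153 CPM in the control libraries, and the mutant 3 differences of Cd79b and Ighd were only -0.027 and -0.047 CPM. The lack of a common ratio therefore decides nothing. B cells carried through the sort for naive CD4+ cells stay open as a source. An effect of the mutation on B cell genes within T cells was not tested and stays open too. Of the 11 tested genes of the list, 3 lay above every control in every mutant library. Among them were Cd79a (1.84 CPM in mutant 1) and Blk (0.537 CPM). Ms4a1 had 0 counts in mutant 1 against 1 to 11 in the controls, all near the limit of detection. Ighm was at 119 CPM in mutant 1 against 132 to 153 CPM in the controls. The list level of mutant 1, at 0.0735, lay within the control range.

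The lower glycolysis, ATF4, sterol and histone lists were weighed together, although the groups overlapped for ATF4, where control 2 lay below mutant 2, and did not for G2-M, which is outside these 4. Camera with its preset correlation called 4 of the 4 lists lower without mutant 1 and 4 of the 4 with the B cell covariate. This test called as many lists as in the real split in 8 of the 10 splits, the real one included. A repeated call therefore cannot exclude mutant 1 alone or the B cell share as the source. Without mutant 1 the means were -0.61 for glycolysis, -0.57 for ATF4 and -0.50 for histones. The sterol mean went from -0.62 to -0.36. The means of the 4 lists thus stayed negative without mutant 1, but no test that can decide the question was run on them. With an estimated correlation on all 6 libraries none of the 4 passed (camera adjusted p = 0.736 for each). The oxygen or nutrient supply of the wells stays open, since the hypoxia genes, where control 2 lay 0.00826 above the highest mutant library, were chosen after the glycolysis list was seen and share 4 genes with it, so they decide nothing. An effect of the Sf3b1 mutation or of Cre itself stays open too and was not tested, which would need cells with Cd4-Cre and wild-type Sf3b1.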
